A study of Mus musculus with 12 samples.

How the data were processed

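RNA was measured in CD8 T cells from the spleen of OT-I mice, whose T cells carry a transgenic T cell receptor for an ovalbumin peptide. Per the labels, the cells received a retroviral vector that was empty (control) or carried Batf3, and transduced cells were isolated by flow cytometry. They were then kept for 6 h with IL-15 at 100 ng/ml (non-stimulated) or with plate-bound antibodies to CD3e and CD28 at 1 µg/ml each (stimulated). These 4 groups had 3 libraries each, 12 in all, and the labels call the replicates technical. Standard deviations, standard errors and p-values therefore measure technical spread only, and no value here covers the spread between mice or between transductions. The labels name IL-15 only for the non-stimulated cultures, so the stimulated and non-stimulated groups differ in IL-15 as well as in the antibodies as far as the labels say.

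Per the labels, polyadenylated RNA was taken from 100 ng of total RNA with a stranded kit, amplified over 15 PCR cycles and sequenced from fragments of about 320 bp. The deposited table holds whole-number read counts per Ensembl gene, which the authors made, per the submitters' processing notes, by alignment to GRCm38 with STAR 2.7 and counting with featureCounts. The annotation release, the strand setting and the treatment of reads that align to several places are not given in the sources used here. The table held 55335 genes and 12 columns, each of which matched 1 sample. Of the gene identifiers, 55154 matched GENCODE M21 (GRCm38), from which coordinates were taken, and 181 did not. Symbols and biotypes are those of the deposited table.

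Total counts lay between 14211564 and 14468231 per library. On the scale of CPM used here (read counts scaled to a common library size), a count of 3 stood for between 0.191 and 0.229 CPM in a single library. Folds for genes with no counts in control non-stimulated cells use a floor of 3 counts over the group, 0.0663 CPM. Floors and intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. CPM values use library sizes scaled with TMM factors, without a pseudocount, and are given as the mean ± SD of 3 libraries.

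Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with edgeR's filterByExpr at its default settings, which left 15702 genes. A model with 4 group means and 8 residual degrees of freedom was fitted to all 12 libraries by quasi-likelihood with robust dispersion. Of its contrasts, 2 compared Batf3 with control cells, in non-stimulated and in stimulated cultures, and 2 compared stimulated with non-stimulated cells, for each vector. The last contrast, the vector by stimulation interaction, is the Batf3 effect in stimulated cells minus the Batf3 effect in non-stimulated cells. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes of a contrast, and a gene was called at an adjusted p under 0.05. A second tier counted called genes with an absolute log2 change of at least 1. Log2 changes are given ± SE, taken from the information matrix of the fit with the moderated quasi-dispersion and never below the counting error, with n = 3 libraries per group, and medians and means of lists are log2 changes as well.

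The lists comprised 33 sets of T cell, stress, metabolic and cell cycle genes and of markers of other cell types that a sort could let through. They were tested with camera (limma 3.58.1, two-sided, preset inter-gene correlation of 0.01), which compares a list with all other genes, with Benjamini-Hochberg adjustment over the 33 lists of a contrast. Beside each count of called members stands the count adjusted over the list alone. Every camera result was also computed with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance without comparing them with other genes. Where a call was lost with the estimated correlation, that p stands beside it. For the effect of the vector, the 2 lists that hold Batf3 are reported without it. This alternative, and that of leaving out 1 library in the list tests, were chosen after the results were seen.

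The comparisons, the lists, the rule for named genes and all alternatives but those were fixed before the data were examined. For the 2 Batf3 contrasts and for stimulation of control cells, the rule took the 10 largest rises and the 10 largest falls. These came from called genes with a mean of at least 10 CPM in the higher group and no overlap between the 3 libraries of each group. Predicted models, clone names and receptor or antibody segments were left out. For the interaction it took the 8 largest changes in each direction at 10 CPM or more, without the separation rule. From each list and contrast it took up to 2 called members in each direction with at least 1 CPM, and 22 genes were always named. Genes withheld for evaluation are not reported here. Near-identical copies occur in the granzyme, Klra, Bcl2a1 and haemoglobin clusters, so counts of single members with such a copy are uncertain.

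The alternatives were RLE factors, library size without factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma-voom, the replicate number as a block, only the 6 libraries compared, an adjusted p under 0.01, and each of the 12 libraries left out in turn. The procedure was also tested on simulated data of 14932 genes with the same 4 groups of 3 libraries. All groups were drawn from the means of control non-stimulated cells, with the same spread for every gene and no response to stimulation. Changed genes were drawn only from genes above a count limit. The shares called therefore do not cover genes at low counts or cells that respond to stimulation. At a true 2-fold change, 98% of changed genes were called for Batf3 in non-stimulated cells, 96% for Batf3 in stimulated cells and 88% for the interaction. Sequence reads were not available, so transcript isoforms, the vector's own transcript and alignment settings were not analysed here.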

Results

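Gene expression was measured by RNA-seq in 12 libraries of OT-I CD8 T cells, 3 for each combination of vector (control or Batf3) and culture (non-stimulated or stimulated for 6 h through CD3 and CD28). BATF3 is a basic leucine zipper transcription factor of the AP-1 family, best known for its role in the development of cross-presenting dendritic cells. The title of the series names CD8 T cell memory, and the comparisons ask which genes the Batf3 vector changed in each culture and how it altered the response to stimulation. Total counts lay between 14211564 and 14468231 per library. Genes with at least 1 count numbered 21919 ± 54 in control non-stimulated cells, 23286 ± 88 in Batf3 non-stimulated cells, 22386 ± 52 in control stimulated cells and 23006 ± 116 in Batf3 stimulated cells (SD, n = 3). The mean share of counts from mitochondrially encoded genes in these groups was 1.94, 2.23, 1.99 and 1.83%.

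**Figure D1:**
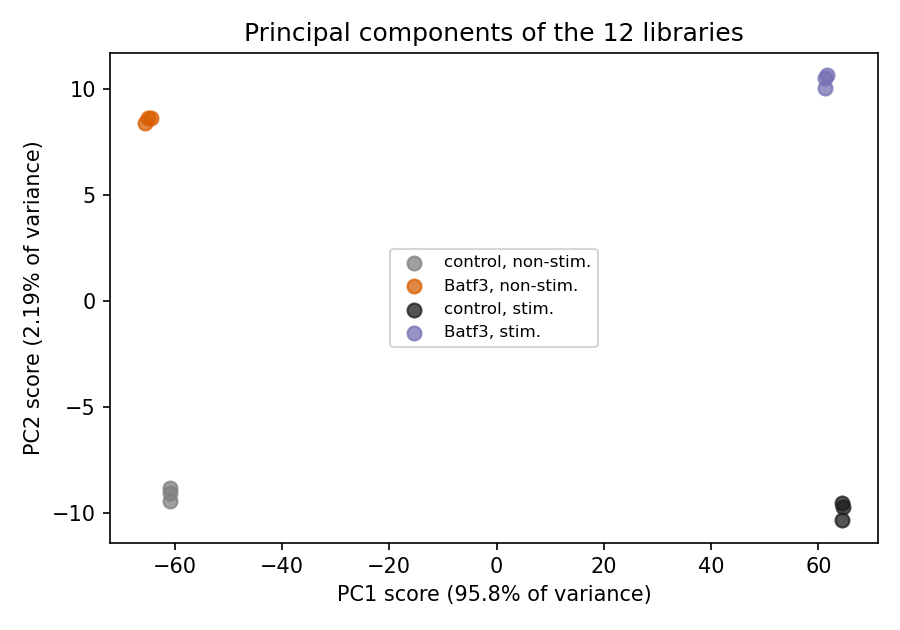
Each point is 1 of the 12 libraries, placed by its scores on the first principal component (x axis, 95.8% of the variance of 1000 genes) and the second (y axis, 2.19%), with colour for the 4 groups. The first axis separates stimulated from non-stimulated libraries, and on the second the 6 control libraries lie between -10.34 and -8.8 and the 6 Batf3 libraries between 8.39 and 10.65.

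Batf3 itself (ENSMUSG00000026630, chromosome 1, 191097847 to 191108945, GRCm38) was compared first, as a check of the labels. In non-stimulated cells its level was 6.77 ± 0.833 CPM with the control vector and 470.4 ± 3.68 CPM with the Batf3 vector (SD, n = 3), a log2 change of 6.12 ± 0.09 (SE). In stimulated cells it was 18.4 ± 0.735 and 427 ± 11.9 CPM, a log2 change of 4.54 ± 0.06. The 3 Batf3 libraries of each culture lay above its 3 control libraries, with adjusted p = 3.96e-68 and 6.89e-64 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the control vector, stimulation raised Batf3 by 1.44 ± 0.10 on the log2 scale. Gene counts do not separate the transcript of the vector from that of the cell's own gene.

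In non-stimulated cells the Batf3 vector raised Il7r, the alpha chain of the IL-7 receptor on which naive and memory T cells depend for survival, from 36.5 ± 1.83 to 134 ± 5.71 CPM (SD, n = 3), a log2 change of 1.87 ± 0.07. Foxp3, the lineage factor of regulatory T cells, rose from 0.619 ± 0.327 to 11.8 ± 0.384 CPM (4.23 ± 0.32). Slamf6, a surface receptor of stem-like T cells, rose from 28.6 ± 2.00 to 103 ± 1.86 CPM (1.85 ± 0.05). Tlr7, an endosomal sensor of single-stranded RNA, fell from 22.3 ± 1.05 to 2.69 ± 0.448 CPM (-3.05 ± 0.15). Eomes, a T-box factor of memory CD8 T cells and NK cells, fell from 329 ± 5.47 to 152 ± 2.01 CPM (-1.12 ± 0.03). All 22 tested genes of the type I interferon list fell, and all 22 genes of the mitosis list rose. Il7r lies at 9505788 to 9530176 on chromosome 15, Foxp3 at 7573644 to 7595245 on X, Tlr7 at 167304929 to 167330558 on X and Eomes at 118478212 to 118486132 on chromosome 9 (GRCm38).

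**Figure D2:**
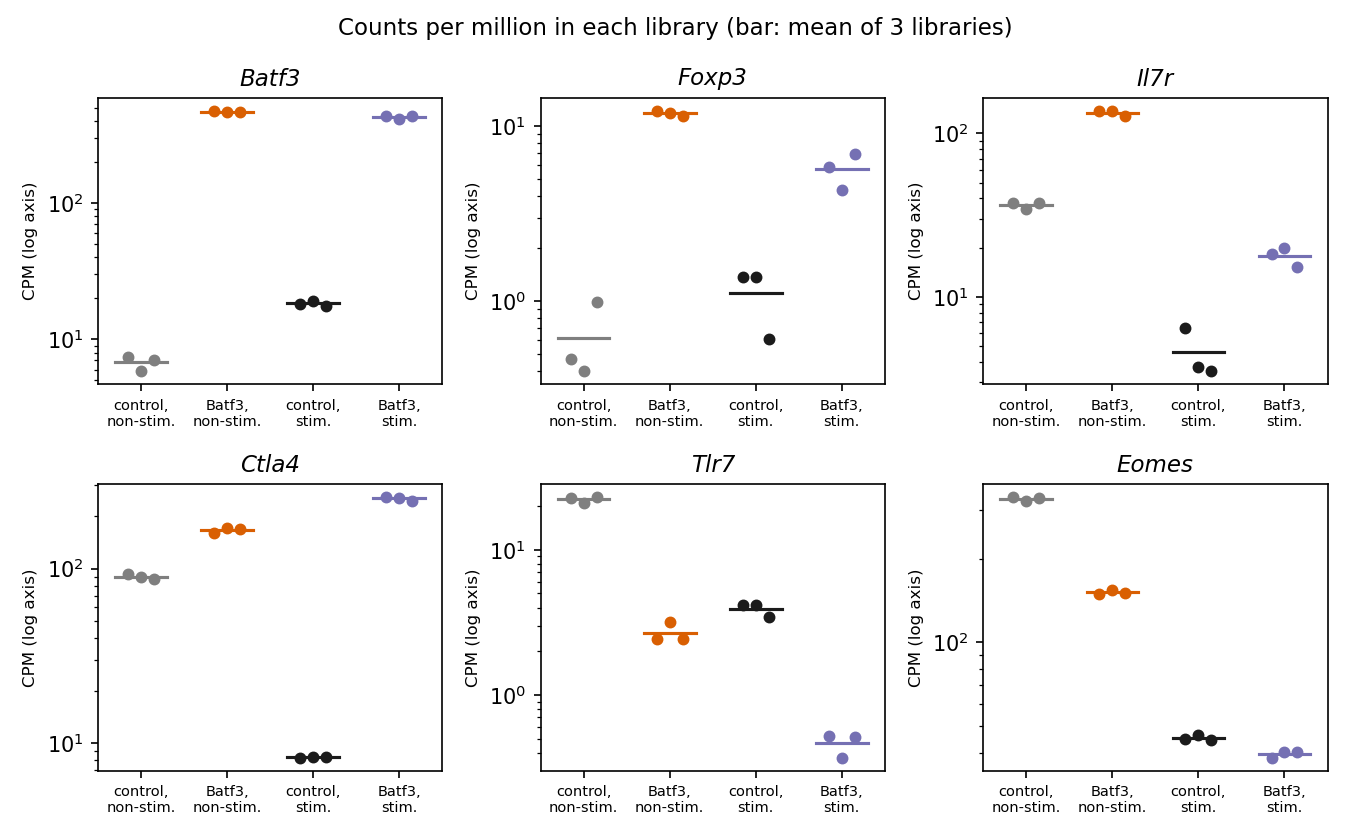
Each panel shows 1 gene, with points for single libraries in CPM on a log axis and a bar at the mean of 3 libraries for each of the 4 groups. Batf3, Foxp3 and Il7r are higher and Tlr7 is lower with the Batf3 vector in both cultures, while Ctla4 reaches a mean of 252 CPM in Batf3 stimulated cells against 8.35 CPM in control stimulated cells.

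Further large rises in non-stimulated cells were those of Rasgrf1, an exchange factor for RAS (4.18 ± 0.31), the long noncoding RNA Miat (3.26 ± 0.23) and Ret, a receptor tyrosine kinase (1.73 ± 0.13). Gpld1, a phospholipase that cleaves GPI anchors, rose by 1.71, Pcyt1b, an enzyme of phosphatidylcholine synthesis, by 1.69, and the transcription factor Grhl3 by 1.64. Among large falls, Sdc3, a heparan sulfate proteoglycan, changed by -1.92 ± 0.05, and Mpeg1, which encodes the pore-forming protein perforin-2, by -1.76 ± 0.12. Car2, a carbonic anhydrase, changed by -1.65, Asb2, a subunit of a ubiquitin ligase, by -1.48, and Bcat1, a transaminase of branched-chain amino acids, by -1.27. Lrrc32, which holds latent TGF-beta on the surface of regulatory T cells, changed by -1.25, Tpst1 by -1.35, Ccn3 by -1.31 and Gpsm1 by -1.31.

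Of the memory-associated genes, 12 of 20 rose and 3 fell (the same counts adjusted over the list alone). The memory list had a median of 0.19 (camera adjusted p = 4.41e-09). Tcf7, which encodes the memory factor TCF-1, changed by -0.20 ± 0.03, against the direction of Il7r and Slamf6. Among the transcription factors of helper lineages, 9 of 17 rose and 2 fell (9 and 3 adjusted over the list alone). The helper-lineage list had a median of 0.14 (camera adjusted p = 1.62e-07), with Runx1 at 1.69 ± 0.16 beside Foxp3. Of the markers of CD4 T cells, 5 of 7 rose and 0 fell (the same counts adjusted over the list alone). This list shares Foxp3 and Zbtb7b with the helper-lineage list and Icos and Cd40lg with the list of costimulatory receptors. These lists are therefore not independent of each other. The CD4 list had a median of 0.79 (camera adjusted p = 4.36e-07), and its member Cd40lg rose by 1.45 ± 0.41. Cd4 itself, too low to be tested, stood at 0.221 ± 0.192 CPM with the control vector and 0.149 ± 0.0742 CPM with the Batf3 vector. In the homing and residency list, 10 of 20 rose and 4 fell (the same counts adjusted over the list alone). The homing list had a median of 0.24 (camera adjusted p = 0.000865). There P2rx7, a receptor for extracellular ATP, rose by 1.76 ± 0.24 and the chemokine receptor Ccr8 by 1.76 ± 0.45, while Ccr2 changed by -0.31 ± 0.03.

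Of the effector-associated genes, 8 of 20 rose and 10 fell (the same counts adjusted over the list alone). The effector list had a median of -0.09 (camera adjusted p = 0.705) and a mean of -0.23, while camera's direction was up. Gzmb, the main cytotoxic granzyme, fell from 2816 ± 23.9 to 1817 ± 20.9 CPM (-0.63 ± 0.02), and Prf1, which encodes perforin, rose by 0.52 ± 0.08. The granzyme genes Gzma and Gzmk rose from 44.0 to 124 and from 1.83 to 7.08 CPM. Tbx21, the effector factor T-bet, rose by 0.14 ± 0.04, and Prdm1, which encodes BLIMP-1, by 0.88 ± 0.11. Klrg1, a receptor of terminal effector cells, stood at 0.442 ± 0.139 and 0.405 ± 0.16 CPM, too low to be tested. In the list of cytokines and chemokines, 1 of 25 rose and 12 fell (the same counts adjusted over the list alone). The cytokine list had a median of -0.26 (camera adjusted p = 0.000346). Ccl5 rose by 0.66 ± 0.03, while Tnfsf11, the ligand RANKL, changed by -1.42 ± 0.16 and Tnf by -0.44 ± 0.04. Il2 stood at 3.87 ± 0.732 and 4.01 ± 0.420 CPM and was not called. Ifng stood at 14.7 ± 1.10 and 15.9 ± 1.53 CPM and was not called with TMM factors, but was with library sizes alone (0.20).

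Of the inhibitory receptors and exhaustion factors, 5 of 18 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of -0.03, which was 0.04 with library sizes alone, a mean of 0.10 and camera adjusted p = 0.209. Ctla4, an inhibitory receptor that competes with CD28, rose from 90.0 ± 3.10 to 166 ± 4.93 CPM (0.88 ± 0.04), and Pdcd1, which encodes PD-1, rose by 0.39 ± 0.08, while Cd160 changed by -0.54 ± 0.05. Among costimulatory receptors, 6 of 13 rose and 3 fell (8 and 3 adjusted over the list alone). The costimulatory list had a median of 0.16 (camera adjusted p = 0.0282, and adjusted p = 0.0711 with an estimated correlation), with Icos at 0.79 ± 0.04 and Tnfrsf9 at -0.23 ± 0.03. In the list of cytokine receptors and their regulators, 9 of 22 rose and 8 fell (the same counts adjusted over the list alone). The cytokine receptor list had a median of 0.03 (camera adjusted p = 0.00929, and adjusted p = 0.116 with an estimated correlation), with Il6ra at 0.69 ± 0.08 and Il10ra at -0.66 ± 0.04. In fits that left out 1 library, the median of this list was 0.00 to 0.05. Of the genes induced early by the T cell receptor, 5 of 25 rose and 14 fell (6 and 15 adjusted over the list alone). The early-gene list had a median of -0.17 (camera adjusted p = 0.01, and adjusted p = 0.185 with an estimated correlation). There Cd69, an early activation marker, changed by -0.63 ± 0.03 and the phosphatase gene Dusp4 by -0.71 ± 0.09, while Nr4a1 stood at 27.6 ± 0.948 and 26.7 ± 0.560 CPM and was not called. For the receptor complex and CD8 identity, 1 of 17 rose and 10 fell (the same counts adjusted over the list alone). The receptor-complex list had a median of -0.09 (camera adjusted p = 0.00606, and adjusted p = 0.116 with an estimated correlation), with Cd8b1 at 0.21 ± 0.03 and Cd6 at -0.76 ± 0.04. The NK-type receptors had a median of 0.07 against a camera direction of down: 4 of 11 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.969), with Crtam at -1.31 ± 0.13.

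In the list of AP-1 and BATF-IRF partners, leaving out Batf3 itself, 4 of 15 rose and 7 fell (4 and 9 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.33). Fos rose by 0.56 ± 0.09, Irf8 changed by -0.59 ± 0.04 and Junb by -0.25 ± 0.03, while Batf stood at 19.6 ± 0.411 and 20.5 ± 0.136 CPM and was not called. Of the pro-apoptotic genes, 4 of 18 rose and 5 fell (4 and 5 adjusted over the list alone), with a median of -0.06, 0.02 with library sizes alone, and camera adjusted p = 0.705. Pmaip1, the BH3-only protein NOXA, rose by 0.44 ± 0.06 and Casp8 changed by -0.44 ± 0.03. Bcl2l11, the BH3-only protein BIM, stood at 234 ± 3.88 and 223 ± 3.26 CPM and was not called, but it was without replicate 3 of Batf3 stimulated cells (-0.07, adjusted p = 0.037 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the anti-apoptotic factors, 3 of 14 rose and 6 fell (4 and 7 adjusted over the list alone), with a median of -0.06, 0.02 with library sizes alone, and camera adjusted p = 0.515. There the kinase gene Pim1 rose by 0.35 ± 0.03.

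The interferon list, genes that type I interferon induces, had a median log2 change of -0.55 (camera adjusted p = 8.14e-60; 22 of 22 fell adjusted over the list alone), with Oas2 at -1.17 ± 0.05 and Ifi44 at -1.74 ± 0.18. The mitosis list had a median of 0.38 (camera adjusted p = 3.44e-20; 22 of 22 rose adjusted over the list alone), with the proliferation marker Mki67 at 0.77 ± 0.03 and Cenpf at 0.55 ± 0.05. In contrast, of the DNA replication genes 3 of 20 rose and 12 fell (4 and 12 adjusted over the list alone). The replication list had a median of -0.16 (camera adjusted p = 0.00929). The helicase subunits Mcm2 and Mcm6 changed by -0.62 ± 0.03 and -0.52 ± 0.03, and Rrm2, a subunit of ribonucleotide reductase, rose by 0.46 ± 0.03. For MYC targets and ribosome biogenesis, 0 of 20 rose and 19 fell (the same counts adjusted over the list alone). The MYC list had a median of -0.48 (camera adjusted p = 1.41e-27). The polyamine enzymes Srm and Odc1 there changed by -0.79 ± 0.04 and -0.66 ± 0.03.

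In all, 2560 of 15702 genes rose and 3615 fell in non-stimulated cells, of which 355 and 136 changed at least 2-fold. At 10 CPM or more the 2-fold counts were 51 and 33. With library sizes alone 3604 genes rose and 2397 fell, so the share of called genes that rose was 60.1% against 41.5% with TMM factors.

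In stimulated cells the Batf3 vector raised Ctla4 from 8.35 ± 0.0471 to 252 ± 5.83 CPM (SD, n = 3), a log2 change of 4.91 ± 0.08, and Icos, a costimulatory receptor of the CD28 family, from 21.5 ± 0.448 to 88.3 ± 2.67 CPM (2.04 ± 0.06). Il7r rose from 4.57 ± 1.65 to 17.8 ± 2.31 CPM (1.96 ± 0.16) and Prdm1 from 3.86 to 13.4 CPM (1.79 ± 0.15). Il23a, the p19 subunit of IL-23, fell from 305 ± 2.12 to 71.4 ± 1.33 CPM (-2.09 ± 0.04), and the regulatory cytokine gene Il10 from 51.3 ± 2.19 to 17.1 ± 1.62 CPM (-1.58 ± 0.08). Bcl2l11 fell from 206 ± 5.13 to 147 ± 3.48 CPM (-0.49 ± 0.03), and Bcl2, the founding anti-apoptotic factor, rose from 74.3 ± 3.21 to 129.6 ± 1.78 CPM (0.80 ± 0.04). Ctla4 lies at 60887000 to 60915832 on chromosome 1, Il23a at 128296139 to 128298752 on chromosome 10 and Bcl2l11 at 128126038 to 128162547 on chromosome 2 (GRCm38).

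Other large rises were those of Gzma (2.65 ± 0.07), the magnesium channel gene Trpm6 (2.26 ± 0.14), the type 2 cytokine gene Il13 (2.14 ± 0.12), Enah, a regulator of actin assembly (1.84 ± 0.13), and Cmklr1, the chemerin receptor (1.82 ± 0.12). Il24, of the IL-10 family, changed by -1.92 ± 0.14, Cxcl16, the ligand of CXCR6, by -1.58 ± 0.10 and the chemokine gene Ccl9 by -1.44 ± 0.04. The interferon-inducible genes Trim30d and Ifi213 changed by -1.48 and -1.33, Nrn1 by -1.45, Sdc3 by -1.35 and Actn1, which crosslinks actin, by -1.41.

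Of the memory-associated genes, 14 of 20 rose and 5 fell (15 and 5 adjusted over the list alone). The memory list had a median of 0.45 (camera adjusted p = 6.7e-11), with Tcf7 at -0.77 ± 0.05 against the direction of Il7r, and Eomes at -0.19 ± 0.05. Among transcription factors of helper lineages, 13 of 17 rose and 1 fell (the same counts adjusted over the list alone). The helper-lineage list had a median of 0.62 (camera adjusted p = 3.08e-22), with Foxp3 at 2.34 ± 0.27 and Maf at 1.74 ± 0.10. As in non-stimulated cells, of the markers of CD4 T cells, which share Foxp3 and Zbtb7b with the helper-lineage list, 5 of 7 rose and 0 fell (the same counts adjusted over the list alone). The CD4 list had a median of 1.63 (camera adjusted p = 7.06e-17). Cd4 stood at 0.305 ± 0.202 and 0.321 ± 0.3 CPM. In the homing and residency list, 13 of 20 rose and 4 fell (14 and 4 adjusted over the list alone). The homing list had a median of 0.47 (camera adjusted p = 1.4e-06), with Ccr8 at 2.15 ± 0.26, P2rx7 at 1.47 ± 0.21 and the integrin gene Itga4 at -0.37 ± 0.09. Of the inhibitory receptors and exhaustion factors, 10 of 18 rose and 3 fell (11 and 3 adjusted over the list alone). The inhibitory list had a median of 0.34 (camera adjusted p = 3.83e-14), with Cd200r1 at 2.04 ± 0.51 and Pdcd1 at 0.30 ± 0.04 beside Ctla4, and Lag3 at -0.46 ± 0.04. Among costimulatory receptors, 9 of 13 rose and 1 fell (the same counts adjusted over the list alone). The costimulatory list had a median of 0.25 (camera adjusted p = 4.11e-20), with Cd40lg at 1.74 ± 0.07. In the list of cytokine receptors and their regulators, 12 of 22 rose and 8 fell (the same counts adjusted over the list alone). The cytokine receptor list had a median of 0.18 (camera adjusted p = 2.05e-05), with Il1rl1, which encodes the IL-33 receptor, at 1.22 ± 0.05 and Il10ra at -0.70 ± 0.07.

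Of the effector-associated genes, 9 of 20 rose and 7 fell (the same counts adjusted over the list alone). The effector list had a median of 0.04 (camera adjusted p = 0.0194, and adjusted p = 0.168 with an estimated correlation). This call was lost without control stimulated replicate 2 (adjusted p = 0.0513). Gzmb rose by 0.30 ± 0.02 and Prf1 by 0.78 ± 0.04, while Ccl4 changed by -0.65 ± 0.03. In the list of cytokines and chemokines, 4 of 25 rose and 14 fell (4 and 16 adjusted over the list alone). The cytokine list had a median of -0.15 (camera adjusted p = 2.02e-15). The interferon gamma gene Ifng fell from 12970 ± 198 to 11710 ± 164 CPM (-0.15 ± 0.02) and Il2 from 3570 ± 15.9 to 3057 ± 70.5 CPM (-0.22 ± 0.02), while Tnf stood at 2065 ± 21.1 and 2035 ± 13.2 CPM and was not called. Of the genes induced early by the T cell receptor, 7 of 25 rose and 11 fell (8 and 11 adjusted over the list alone). The early-gene list had a median of -0.05 (camera adjusted p = 0.0746), with Egr2 at 0.73 ± 0.03, Cd69 at -0.56 ± 0.03 and Nr4a1 not called at 320.5 ± 3.65 and 310.1 ± 8.16 CPM. The early-gene list was called without control stimulated replicate 1 (adjusted p = 0.0316) or 2 (0.0468) and without Batf3 stimulated replicate 1 (0.0479) or 3 (0.0309). For the receptor complex and CD8 identity, 13 of 17 rose and 1 fell (the same counts adjusted over the list alone). The receptor-complex list had a median of 0.14 (camera adjusted p = 4.69e-06). There the signalling chain gene Cd247 rose by 0.85 ± 0.04 and Ptprc, which encodes CD45, by 0.55 ± 0.02. For the NK-type receptors, 5 of 11 rose and 2 fell (the same counts adjusted over the list alone). The NK-type list had a median of 0.34 (camera adjusted p = 0.529), with Klrc1 at 0.34 ± 0.08 and Crtam at -0.30 ± 0.03.

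Of the AP-1 and BATF-IRF partners, again leaving out Batf3, 5 of 15 rose and 7 fell (the same counts adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.454). Jun rose by 0.72 ± 0.04, while Irf4, a partner of BATF factors, changed by -0.51 ± 0.02, Irf8 by -0.74 ± 0.03, Batf by -0.36 ± 0.07 and Junb by -0.20 ± 0.03. Of the pro-apoptotic genes, 8 of 18 rose and 3 fell (the same counts adjusted over the list alone). The pro-apoptotic list had a median of 0.17 (camera adjusted p = 0.429), with Pmaip1 at 0.53 ± 0.06 and Bmf, another BH3-only gene, at -1.25 ± 0.23 beside Bcl2l11. Of the anti-apoptotic factors, 6 of 14 rose and 3 fell (7 and 4 adjusted over the list alone). The anti-apoptotic list had a median of 0.06 (camera adjusted p = 0.153), with Xiap at -0.28 ± 0.06 and Pim1 at -0.25 ± 0.03.

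In the interferon list 2 of 22 rose and 17 fell (2 and 19 adjusted over the list alone). The interferon list had a median of -0.52 (camera adjusted p = 4.91e-14), with Oas2 at -1.26 ± 0.12, Ifi44 at -1.50 ± 0.42 and Ifit1, which rose, at 0.23 ± 0.05. The proliferation lists rose together. For mitosis 22 of 22 rose and 0 fell (the same counts adjusted over the list alone). The mitosis list had a median of 0.63 (camera adjusted p = 2.45e-22), with Mki67 at 1.12 ± 0.04 and Hmmr at 0.92 ± 0.10. For DNA replication 18 of 20 rose and 0 fell (19 and 0 adjusted over the list alone). The replication list had a median of 0.47 (camera adjusted p = 1.02e-16), with Rrm2 at 0.75 ± 0.06 and Gins2 at 0.72 ± 0.16. For MYC targets and ribosome biogenesis 0 of 20 rose and 7 fell (0 and 8 adjusted over the list alone). The MYC list had a median of -0.05 (camera adjusted p = 0.0338, and adjusted p = 0.102 with an estimated correlation), which was 0.00 with library sizes alone, with Nop56 at -0.19 ± 0.03.

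In all, 2331 genes rose and 2300 fell in stimulated cells, of which 384 and 131 changed at least 2-fold. At 10 CPM or more the 2-fold counts were 67 and 33. With library sizes alone 2979 genes rose and 1561 fell, so the share of called genes that rose was 65.6% against 50.3% with TMM factors.

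**Figure D3:**
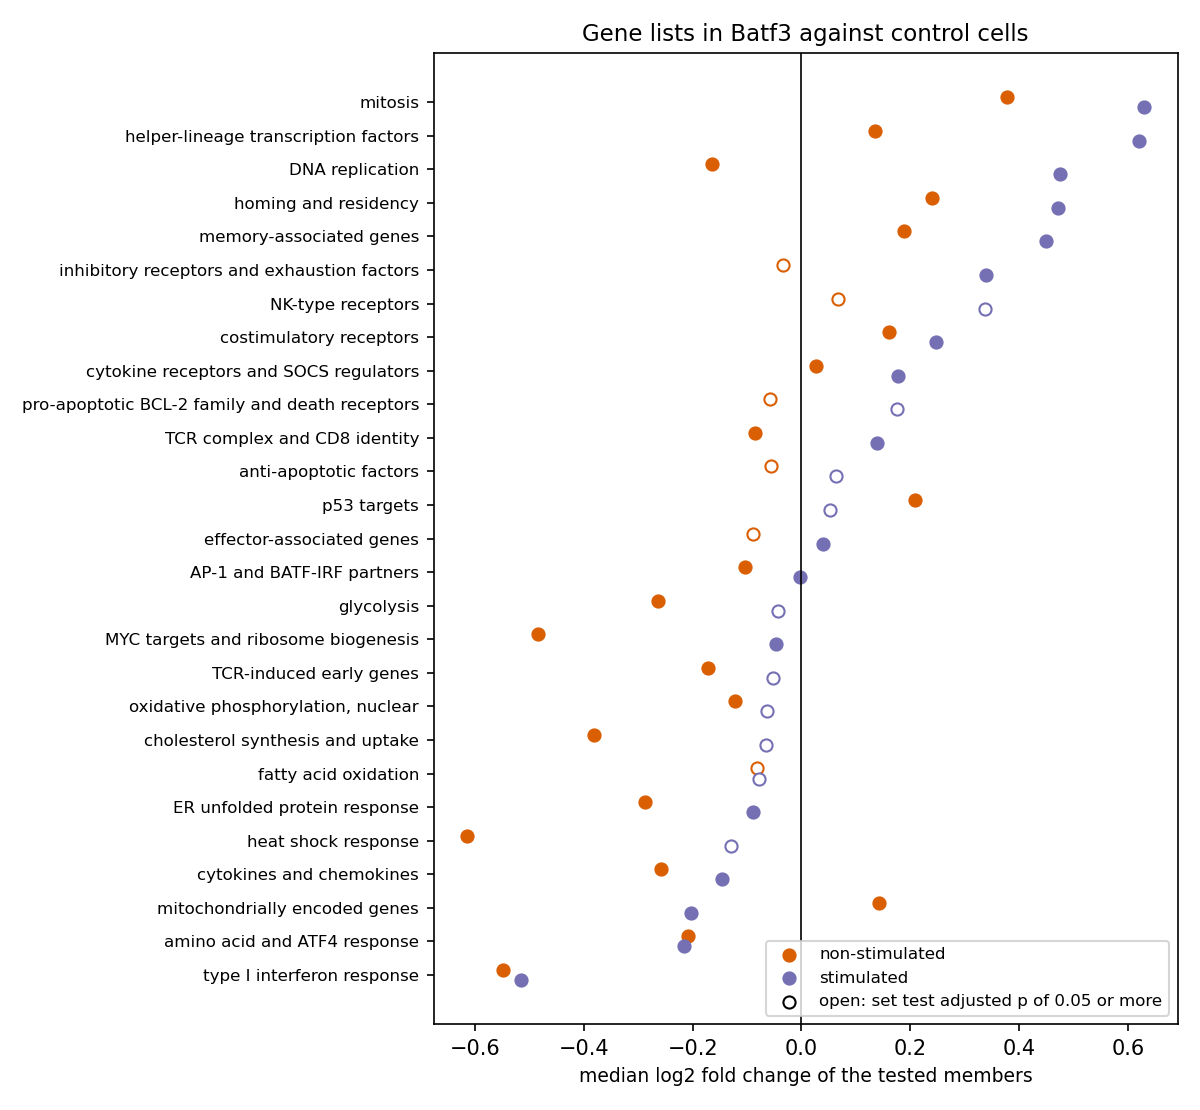
Points give the median log2 change of the tested genes of each of 27 lists (x axis) for Batf3 against control cells, in non-stimulated (orange) and stimulated (purple) cultures, and open symbols mark lists with a camera adjusted p of 0.05 or more. The AP-1 list is drawn with Batf3 included, and without it its camera adjusted p was 0.33 and 0.454. The interferon list lies at -0.55 and -0.52 and the mitosis list at 0.38 and 0.63, while the DNA replication list lies at -0.16 and 0.47.

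The Batf3 effects in the 2 cultures shared no library and were compared across 15702 genes. Sharing no library does not make them independent, because per the labels the cells were transduced and sorted before these cultures. A difference between the control and Batf3 transductions could appear in both cultures, and the overlap does not separate it from an effect of the vector. Pearson's r of the log2 changes was 0.415 and Spearman's rho 0.406, across genes, which are not independent replicates. Genes that rose in both cultures numbered 1097, against 380 if the calls were independent, and genes that fell in both 1328, against 530. With library sizes alone 1571 rose and 731 fell in both. Opposite calls were made for 362 genes, all of them with an interaction call. At least 2-fold in both, 107 genes rose and 29 fell: Il7r, Foxp3 and Gzma were among the former, and Tlr7, Sdc3 and Mpeg1 among the latter.

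Stimulation of control cells, which also differed in IL-15 as far as the labels say, raised Ifng from 14.7 ± 1.10 to 12970 ± 198 CPM (SD, n = 3), a log2 change of 9.79 ± 0.06, Il2 from 3.87 ± 0.732 to 3570 ± 15.9 CPM (9.85 ± 0.11) and Tnf from 71.2 ± 4.49 to 2065 ± 21.1 CPM (4.86 ± 0.03). Nr4a1, an early target of the T cell receptor, rose by 3.54 ± 0.05, Cd69 by 1.16 ± 0.03, Irf4 by 3.56 ± 0.03 and Pdcd1 by 3.88 ± 0.07. Il7r fell from 36.5 ± 1.83 to 4.57 ± 1.65 CPM (-2.99 ± 0.15) and S1pr1, the receptor for exit from lymphoid tissue, from 157 ± 3.75 to 2.94 ± 0.392 CPM (-5.73 ± 0.14). Of 25 tested cytokines and chemokines 22 rose, and all 22 interferon-response, all 22 mitosis and all 20 DNA replication genes fell.

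The cytokine gene Il3 rose from 0.0885 ± 0.0766 to 2018 ± 16.0 CPM (14.34 ± 0.72), the chemokine gene Ccl1 by 10.92 ± 0.16, Il1a by 12.13 ± 0.63 and Ccl9 by 11.46 ± 0.65. Of other genes with large rises, 5 had no counts in control non-stimulated cells, so their folds are lower bounds against a floor of 3 counts over the group. Inhba, a subunit of activin, was at least 901-fold higher, Idi2, an isomerase of isoprenoid synthesis, at least 767-fold, Pdzk1ip1 at least 685-fold, Tpbg at least 208-fold and Penk, the precursor of enkephalins, at least 181-fold. Cth, an enzyme of cysteine synthesis, had 1 count over the group in non-stimulated cells and stood at 72.6 ± 3.60 CPM in stimulated cells. Large falls were those of Mettl7a1 (-6.04 ± 0.59), the prothrombinase gene Fgl2 (-5.87 ± 0.10), Nsg2 (-5.66 ± 0.24), Art2b, an ADP-ribosyltransferase (-5.50 ± 0.49), and Ifit1bl1 (-5.49 ± 0.10). Baiap3, Depdc1b, Pimreg and Dpp4, which encodes the peptidase CD26, changed by -5.46, -5.38, -5.30 and -5.25.

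For cytokines and chemokines 22 of 25 rose and 2 fell (the same counts adjusted over the list alone). The cytokine list had a median of 5.99 (camera adjusted p = 1.66e-68). For genes induced early by the T cell receptor 24 of 25 rose and 1 fell (the same counts adjusted over the list alone). The early-gene list had a median of 2.28 (camera adjusted p = 2.82e-43), with Tnfrsf4, which encodes OX40, at 6.08 ± 0.09. For MYC targets 20 of 20 rose and 0 fell (the same counts adjusted over the list alone). The MYC list had a median of 1.73 (camera adjusted p = 1.51e-28), with Srm at 2.61 ± 0.03. For the amino acid and ATF4 response 18 of 20 rose and 2 fell (the same counts adjusted over the list alone). The ATF4 list had a median of 2.02 (camera adjusted p = 1.17e-19). For effector genes 13 of 20 rose and 7 fell (the same counts adjusted over the list alone). The effector list had a median of 1.19 (camera adjusted p = 2.73e-18), with Prf1 at 3.08 ± 0.07, Gzmb at 0.34 ± 0.02 and the cathepsin gene Ctsw at -1.72 ± 0.03. For inhibitory receptors 11 of 18 rose and 5 fell (the same counts adjusted over the list alone). The inhibitory list had a median of 1.56 (camera adjusted p = 9.4e-08), with Havcr2, which encodes TIM-3, at 5.73 ± 0.10 and Ctla4 at -3.43 ± 0.08. For AP-1 and BATF-IRF partners 13 of 16 rose and 3 fell (the same counts adjusted over the list alone). The AP-1 list had a median of 1.36 (camera adjusted p = 2.16e-06), with Batf at 0.88 ± 0.07, Junb at 1.27 ± 0.03 and Jun at -0.26 ± 0.04. Of the unfolded protein response genes 12 of 15 rose and 2 fell (the same counts adjusted over the list alone). The unfolded protein list had a median of 1.16 (camera adjusted p = 1.4e-06). Of costimulatory receptors 8 of 13 rose and 4 fell (the same counts adjusted over the list alone). The costimulatory list had a median of 0.49 (camera adjusted p = 0.00486). Of heat shock genes 8 of 10 rose and 2 fell (the same counts adjusted over the list alone). The heat shock list had a median of 1.19 (camera adjusted p = 0.00119, and adjusted p = 0.0755 with an estimated correlation). For helper-lineage factors 11 of 17 rose and 6 fell (the same counts adjusted over the list alone). The helper-lineage list had a median of 0.54 (camera adjusted p = 0.0403, and adjusted p = 0.0755 with an estimated correlation), with Ahr at 3.87 ± 0.13.

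Lists that fell included the interferon response, where 0 of 22 rose and 22 fell (the same counts adjusted over the list alone). The interferon list had a median of -2.65 (camera adjusted p = 1.98e-34), with Mx1 at -4.04 ± 0.04. For mitosis 0 of 22 rose and 22 fell (the same counts adjusted over the list alone). The mitosis list had a median of -2.48 (camera adjusted p = 1.67e-19). For DNA replication 0 of 20 rose and 20 fell (the same counts adjusted over the list alone). The replication list had a median of -1.60 (camera adjusted p = 3.09e-09). For memory genes 6 of 20 rose and 14 fell (the same counts adjusted over the list alone). The memory list had a median of -1.17 (camera adjusted p = 3.22e-07), with Tcf7 at -1.92 ± 0.04, Eomes at -2.87 ± 0.04 and Slamf6 at 1.85 ± 0.05. For homing and residency 6 of 20 rose and 14 fell (the same counts adjusted over the list alone). The homing list had a median of -1.48 (camera adjusted p = 0.00119), with Ccr2 at -4.93 ± 0.08 and Cd44 at 2.81 ± 0.03. For cytokine receptors 6 of 22 rose and 14 fell (6 and 15 adjusted over the list alone). The cytokine receptor list had a median of -0.91 (camera adjusted p = 0.00152, and adjusted p = 0.0755 with an estimated correlation). In the fatty acid oxidation list 4 of 18 rose and 13 fell (the same counts adjusted over the list alone). The fatty acid list had a median of -1.04 (camera adjusted p = 0.00667), with Acadl at -3.47 ± 0.06. For pro-apoptotic genes 4 of 18 rose and 13 fell (the same counts adjusted over the list alone). The pro-apoptotic list had a median of -0.57 (camera adjusted p = 0.0414, and adjusted p = 0.0755 with an estimated correlation). For anti-apoptotic factors 7 of 14 rose and 5 fell (the same counts adjusted over the list alone). The anti-apoptotic list had a median of 0.11 (camera adjusted p = 0.00667, and adjusted p = 0.104 with an estimated correlation), which was -0.08 with library sizes alone, with Bcl2 at -1.84 ± 0.04. In all, 6220 genes rose and 6384 fell, of which 2676 and 3786 changed at least 2-fold. With library sizes alone 5086 rose and 7443 fell. Library sizes alone shifted the median of all genes by -0.19 in this comparison and by -0.21 with the Batf3 vector.

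In Batf3 cells, stimulation raised the same genes: the cytokine gene Ifng rose by 9.52 ± 0.06, Il2 by 9.57 ± 0.11 and Tnf by 5.28 ± 0.03, and the early gene Nr4a1 by 3.54 ± 0.05, while Il7r fell by 2.91 on the log2 scale. For cytokines and chemokines 23 of 25 rose and 2 fell (the same counts adjusted over the list alone). The cytokine list had a median of 6.65 (camera adjusted p = 4.98e-61). For genes induced early by the T cell receptor 23 of 25 rose and 1 fell (the same counts adjusted over the list alone). The early-gene list had a median of 2.44 (camera adjusted p = 7.17e-41). For MYC targets 20 of 20 rose and 0 fell (the same counts adjusted over the list alone). The MYC list had a median of 2.04 (camera adjusted p = 3.59e-35). Of the interferon genes 1 of 22 rose and 20 fell (the same counts adjusted over the list alone). The interferon list had a median of -2.51 (camera adjusted p = 1.88e-23). For mitosis 0 of 22 rose and 22 fell (the same counts adjusted over the list alone). The mitosis list had a median of -2.19 (camera adjusted p = 1.21e-18). For DNA replication 0 of 20 rose and 19 fell (the same counts adjusted over the list alone). The replication list had a median of -0.88 (camera adjusted p = 0.000403). For memory genes 4 of 20 rose and 13 fell (the same counts adjusted over the list alone). The memory list had a median of -1.22 (camera adjusted p = 9.37e-07). For effector genes 13 of 20 rose and 6 fell (the same counts adjusted over the list alone). The effector list had a median of 1.40 (camera adjusted p = 5.85e-19). In all, 6477 genes rose and 6508 fell, of which 2953 and 3828 changed at least 2-fold. With library sizes alone 5254 rose and 7525 fell. Across both vectors 5754 genes rose, 5878 fell and 108 were called in opposite directions. Over 6628 genes, the total least squares slope of the response in Batf3 cells on that in control cells was 1.005 and r was 0.965.

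The interaction asked where the Batf3 effect differed between the cultures, and of named genes that reach 10 CPM in at least 1 group Ctla4 had the largest positive value. It fell from 90.0 ± 3.10 to 8.35 ± 0.0471 CPM on stimulation with the control vector but rose from 166 ± 4.93 to 252 ± 5.83 CPM with the Batf3 vector (SD, n = 3), an interaction of 4.03 ± 0.09 on the log2 scale. Interactions were also positive for Icos (1.26 ± 0.07) and for Stat4, a transducer of IL-12 signals (1.27 ± 0.08). Il23a had an interaction of -2.80 ± 0.49, with 0.309 and 0.512 CPM before and 305 and 71.4 CPM after stimulation in control and Batf3 cells. Foxp3 (-1.90 ± 0.42) and Rasgrf1 (-2.32 ± 0.59), which rose with the Batf3 vector in both cultures, rose less in stimulated cells.

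Other large positive values were those of the cyclin gene Ccnd1 (2.63 ± 0.46), Arsb, a lysosomal sulfatase (1.82 ± 0.12), the phosphatase gene Dusp14 (1.75 ± 0.31), the zinc finger factor Casz1 (1.71 ± 0.18) and Map2k3os (1.57 ± 0.40). Large negative ones were those of Il24 (-1.80 ± 0.37), the sulfatase gene Sulf2 (-1.73 ± 0.41) and the transcription factor Klf3 (-1.63 ± 0.16). Among genes always named, the interaction was 0.93 ± 0.06 for Eomes, 0.93 ± 0.03 for Gzmb, 0.91 ± 0.18 for Prdm1, 0.82 ± 0.06 for Jun and 0.70 ± 0.05 for Bcl2. It was -0.42 ± 0.05 for Bcl2l11, -0.57 ± 0.06 for Tcf7, -0.40 ± 0.04 for Irf4 and -0.43 ± 0.10 for Batf. Il7r (0.09 ± 0.18), Pdcd1 (-0.10 ± 0.09), Tbx21 (-0.04 ± 0.05), Nr4a1 (0.00 ± 0.07) and Cd69 (0.07 ± 0.04) had no interaction call.

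By lists, the interactions of DNA replication genes were the clearest: 16 of 20 were positive and 0 negative, with 17 and 0 adjusted over the list alone (median 0.59, camera adjusted p = 3.72e-34), with Mcm2 at 1.13 ± 0.05 and Mcm6 at 1.07 ± 0.05. For MYC targets 19 of 20 were positive and 0 negative, with the same counts adjusted over the list alone (median 0.38, camera adjusted p = 8.73e-29), with Srm at 0.63 ± 0.05. For heat shock genes 9 of 10 were positive and 0 negative, with 10 and 0 adjusted over the list alone (median 0.47, camera adjusted p = 6.72e-14). For the T cell receptor complex 14 of 17 were positive and 0 negative, with the same counts adjusted over the list alone (median 0.23, camera adjusted p = 1.45e-15), with Cd247 at 0.82 ± 0.05. For inhibitory receptors 9 of 18 were positive and 1 negative, with 10 and 1 adjusted over the list alone (median 0.40, camera adjusted p = 4.81e-10). For costimulatory receptors 5 of 13 were positive and 1 negative, with the same counts adjusted over the list alone (median 0.15, camera adjusted p = 2.63e-07). Leaving out 1 library gave that list a median of 0.11 to 0.25. For helper-lineage factors 9 of 17 were positive and 2 negative, with the same counts adjusted over the list alone (median 0.27, camera adjusted p = 0.00128). For effector genes 10 of 20 were positive and 3 negative, with 11 and 3 adjusted over the list alone (median 0.22, camera adjusted p = 1.26e-05). For NK-type receptors 5 of 11 were positive and 0 negative, with the same counts adjusted over the list alone (median 0.35, camera adjusted p = 0.025, and adjusted p = 0.0662 with an estimated correlation), and for NK cell markers 3 of 5 were positive and 0 negative, with the same counts adjusted over the list alone (median 0.93, camera adjusted p = 9.7e-06). For glycolysis 14 of 22 were positive and 0 negative, with 16 and 1 adjusted over the list alone (median 0.23, camera adjusted p = 7.45e-07).

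For mitosis 13 of 22 were positive and 0 negative, with 14 and 0 adjusted over the list alone (median 0.27, camera adjusted p = 1e-04). For the unfolded protein response 7 of 15 were positive and 0 negative, with 8 and 0 adjusted over the list alone (median 0.15, camera adjusted p = 0.00022). For cholesterol synthesis 10 of 23 were positive and 0 negative, with 12 and 0 adjusted over the list alone (median 0.24, camera adjusted p = 0.000868). For the interferon response 9 of 22 were positive and 4 negative, with the same counts adjusted over the list alone (median 0.15, camera adjusted p = 0.000868). Its median was 0.05 to 0.16 in fits that left out 1 library. For mitochondrially encoded genes 0 of 13 were positive and 4 negative, with 0 and 6 adjusted over the list alone (median -0.30, camera adjusted p = 4.81e-10, and adjusted p = 0.159 with an estimated correlation). Without Batf3 stimulated replicate 3, in which these genes held 1.64% of counts against 1.96 and 1.89% in the other 2 replicates, the median was -0.21 (camera adjusted p = 1.61e-09).

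In all, 2296 interactions were positive and 954 negative, of which 130 and 114 were at least 2-fold. The median interaction over all genes was 0.05. With library sizes alone 1878 were positive and 1126 negative, so the positive share of called genes was 62.5% against 70.6% with TMM factors. With RLE factors the counts were 2085 and 1039. Without a filter on low counts 1524 were positive and 1107 negative, and at an adjusted p under 0.01 these were 1615 and 602. Among called genes with a mean response to stimulation, 1469 were induced more and 335 less with the Batf3 vector, and 531 were repressed more and 728 less. Of these genes 34.7% had the smaller response with the Batf3 vector. This share pools opposite patterns, since most induced genes were induced more but most repressed genes were repressed less. It does not show a larger response as a whole: the slope over 6628 genes was 1.005.

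Markers of other cell types were measured as lists as well. Of the dendritic cell markers other than Batf3, 3 of 7 rose and 1 fell in non-stimulated cells (3 and 3 adjusted over the list alone), with a median of -0.02, which was 0.05 with library sizes alone (camera adjusted p = 0.72). In stimulated cells 4 rose and 2 fell (the same counts adjusted over the list alone), with a median of 0.70 (camera adjusted p = 0.131). Itgax, which encodes CD11c, rose by 0.91 ± 0.10 and 1.31 ± 0.07, and Cd74, the invariant chain, changed by -0.88 ± 0.10 and -0.45 ± 0.06. The NK cell markers include Gzma and Eomes, which CD8 T cells express. In non-stimulated cells 2 of 5 rose and 2 fell (the same counts adjusted over the list alone). The NK cell list had a median of 0.00 (camera adjusted p = 0.755) and a mean of -0.12. In stimulated cells 2 of 5 rose and 1 fell (the same counts adjusted over the list alone). The NK cell list had a median of 0.23 (camera adjusted p = 1.5e-05), and the median was 0.01 to 0.58 in fits that left out 1 library.

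For monocytes, macrophages and granulocytes 3 of 5 rose and 0 fell (the same counts adjusted over the list alone). The myeloid list had a median of 0.39 (camera adjusted p = 0.177) in non-stimulated cells, with Itgam, which encodes CD11b, at 1.29 ± 0.21. In stimulated cells 2 of 5 rose and 1 fell (the same counts adjusted over the list alone). The myeloid list had a median of 0.57 (camera adjusted p = 0.318) and a mean of -0.45. For B cells in non-stimulated cultures 2 of 5 rose and 0 fell (the same counts adjusted over the list alone). The B cell list had a median of -0.12 (camera adjusted p = 0.58), while camera's direction was up. In stimulated cultures 0 of 5 rose and 1 fell (the same counts adjusted over the list alone). The B cell list had a median of 0.36 (camera adjusted p = 0.72), while camera's direction was down. Of the markers of erythroid cells and platelets 2 of 2 rose and 0 fell (the same counts adjusted over the list alone). The erythroid list had a median of 1.27 (camera adjusted p = 0.16) in non-stimulated cells, and the list was called without Batf3 non-stimulated replicate 3 (adjusted p = 0.0412). In stimulated cells 0 of 2 rose and 0 fell (1 and 0 adjusted over the list alone). The erythroid list had a median of 1.29 (camera adjusted p = 0.485). Lyz2, S100a8, Ms4a1, Igkc and Ncr1, abundant transcripts of myeloid, B and NK cells, had 0 counts in all 12 libraries, which allows at most 0.229 CPM in each. Other members of these lists were present, so the markers without counts do not stand for their lists. The B cell marker Ighm held 16338 counts over the control and 18558 over the Batf3 non-stimulated group, and 1993 and 1553 in stimulated cells. The myeloid marker Cd68 held 313 and 426 counts in non-stimulated cells and 215 and 243 in stimulated cells.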

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

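The tests of RNA from CD4 T cells and of scaling over all tested CD4 markers were chosen only after their results were seen. Of all 15702 genes tested, 130 had a positive and 114 a negative interaction call of at least 2-fold. The 299 named genes tested were picked in part by the size of changes in these data, so their share does not describe all genes. Of these 299, 35 had a Batf3 effect that differed between stimulated and non-stimulated cells by such a call, 24 of them positive and 11 negative. The values below are those of named genes. Ctla4 (4.03 on the log2 scale), the cyclin gene Ccnd1 (2.63), the NK-type receptor gene Klrb1c (2.16), Arsb (1.82), Dusp14 (1.75), Casz1 (1.71) and Map2k3os (1.57) had the largest positive values that rest on more than 3 counts in each group and were called without each library in turn. Among genes of T cell function, the interaction was 1.32 for Tnfsf11, 1.27 for Stat4, 1.26 for Icos, 1.15 for Gzma, 1.06 for Egr2, a target of T cell receptor signals, and 1.01 for Crtam. Replication genes were Mcm2 (1.13), Mcm6 (1.07) and Gins2 (1.02). The anti-apoptotic genes Bcl2a1b (1.24) and Bcl2a1d (1.04) have near-identical copies. Bcat1 had 1.13, Asb2 1.13 and Car2 1.10.

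Negative interactions were those of Il23a (-2.80), Rasgrf1 (-2.32), Foxp3 (-1.90), Il24 (-1.80), Sulf2 (-1.73), Klf3 (-1.63), Batf3 itself (-1.58), Actn1 (-1.38) and the chemokine gene Cxcl16 (-1.22). Samd4, an RNA-binding protein gene, had 2.72 but only 3 counts over the Batf3 non-stimulated group. Cth had -3.23, with 1 count over the control non-stimulated group. Its call was lost without control non-stimulated replicate 2 (-2.79) or replicate 3 (-2.78) and without Batf3 non-stimulated replicate 1 (-3.14) or replicate 3 (-2.45). Il10 had -2.09, with 6 and 9 counts over the control and Batf3 non-stimulated groups, and its call was lost without control non-stimulated replicate 2 (-1.78) or replicate 3 (-2.08) and without Batf3 non-stimulated replicate 1 (-1.84) or replicate 3 (-2.09). Stra6, the retinol-binding protein receptor, had 1.87, and its call was lost without control non-stimulated replicate 2 (1.68) or replicate 3 (1.68) and without Batf3 non-stimulated replicate 1 (1.77) or replicate 3 (1.77).

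Other splits of the 12 libraries into 4 groups were used to ask whether the number of interaction calls, 3250, could arise by the grouping alone. Of 60 splits, 2 gave as many, the real one included, but this does not settle whether chance can be excluded. The other splits mix stimulated with non-stimulated libraries, which puts the response to stimulation into the residual spread. The common biological coefficient of variation was 0.407 or more in them, against 0.03 in the real split. Of the splits, 57 gave 0 calls by edgeR, with up to 9287 genes at an unadjusted p under 0.05. The highest of the others had 6609 calls. It set 5 stimulated libraries against 1, but so did a split with 1 call, and what set it apart was not tested. As the replicates are technical, exchanging them also says nothing of chance differences between cultures. For the 4 comparisons of 3 with 3 libraries, the 10 splits of each are too few for a share under 0.05. In fits to the 6 libraries alone, the real split gave 6042 calls for Batf3 in non-stimulated cells, 4524 for Batf3 in stimulated cells, 12205 for stimulation in control cells and 12622 for stimulation in Batf3 cells, and 1 split of 10 in each was as large. The highest of the other splits gave 0 calls by edgeR in each of these, with at most 269, 289, 21 and 38 genes at an unadjusted p under 0.05 in the same order. These splits also mix the real groups, which puts the compared effect into the residual spread, so their 0 calls say nothing of chance.

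Most tested markers of CD4 T cells, such as Foxp3, Icos and Cd40lg, rose in Batf3 cells: 5 of 7 in non-stimulated and 5 in stimulated cells. No list of regulatory T cell genes was tested. Foxp3, Icos and Ctla4 rose in both cultures, while Lrrc32 fell in both (-1.25 ± 0.05 and -0.84 ± 0.06) and Il10 fell in stimulated cells (-1.58 ± 0.08). RNA from CD4 T cells in those libraries is an explanation to weigh, although cells were sorted for transduction. It needs Cd4 to be at least as abundant as Foxp3, but the mean of Cd4 in the 2 Batf3 groups was at most 0.321 CPM, against 11.8 and 5.68 CPM for Foxp3. Scaling factors were weighed as well. With library sizes alone, the median log2 change of all 7 tested CD4 markers was 0.86 in non-stimulated and 1.68 in stimulated cells, against 0.79 and 1.63 with TMM factors. Over called markers alone, which favours large values, it was at least 1.29. Library sizes alone shift all log2 changes up, by a median of 0.075 in non-stimulated and 0.046 in stimulated cells. They could therefore not have removed the rise, and they show only that the shift is small beside it. A change within the CD8 T cells that carry the Batf3 vector may be the source, as a hypothesis found and tested on the same data. The labels call the Batf3 libraries of each group technical replicates and do not say at which step they were split. An effect of the vector therefore cannot be separated here from a difference between cultures or transductions.

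Genes of the type I interferon response were lower in Batf3 cells in both cultures. With library sizes alone the median of the list was -0.47 or lower in both. Leaving out the factors shifted all log2 changes by a median of only 0.075 in non-stimulated and 0.046 in stimulated cells. The factors are thus too small to account for the drop, and this shows no more than that. Removing the trend of log2 change with GC content and transcript length, with a value for 22 of 22 members, left a median of -0.53 in stimulated cells and -0.57 in non-stimulated cells, against -0.52 and -0.55 before. The drop may be a response to BATF3, but a difference in interferon exposure between the control and Batf3 cultures would look alike. With technical replicates alone no biological separation of these is possible.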

How the results depend on the processing

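The tests of lists with Batf3 left out and with 1 library left out were chosen only after the results were seen. Gene results here are those of the 299 named genes tested, over all contrasts. These genes were picked in part by the size of changes in these data, so the shares kept do not describe all genes. Of 1495 such results, 1485 kept their direction and their side of the threshold with RLE factors, 1449 with DESeq2 and 1465 with limma-voom. Without a filter on low counts 1437 did, and at an adjusted p under 0.01 1411 did. With a filter of at least 1 CPM in 3 libraries 1477 of 1485 did, and with only the 6 libraries compared 1132 of 1152. Library sizes alone kept 1401, ended 47 calls, added 35 and reversed 12 signs. Over the 12 fits that left out 1 library, 17420 of 17940 results were kept, 400 calls were lost and 120 gained. Of 165 list results, 146 were kept with an estimated correlation and 108 with fry, which added 55 calls. Leaving out 1 library kept 1953 of 1980 list results, ended 3 calls and added 24. With Batf3 left out of the 2 lists that hold it, all 4 of their camera calls for the Batf3 vector were lost: for AP-1 partners the direction turned down (adjusted p = 0.33 in non-stimulated and 0.454 in stimulated cells), and for dendritic cell markers it stayed up (0.72 and 0.131).

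With library sizes alone, 2397 genes fell in non-stimulated Batf3 cells against 3615, and 731 fell in both cultures against 1328; both moved because all log2 changes shift together without scaling factors, by a median of 0.07 in non-stimulated and 0.05 in stimulated cells. Without a filter 1524 interactions were positive against 2296, while 32686 genes were tested instead of 15702; the cause was not tested. At an adjusted p under 0.01, by its own construction, 602 were negative against 954. Signs that reversed with library sizes alone were those of Thy1 with Batf3 in non-stimulated cells (0.004), and with stimulation of control cells those of Il2rg (-0.01), Stat3 (-0.11), Thy1 (-0.068), Slc2a3 (-0.042) and mt-Co1 (-0.014). With stimulation of Batf3 cells they were those of Ndufb8 (-0.20), mt-Cytb (-0.12), Thy1 (-0.11), Ndufa10 (-0.11), Lss (-0.044) and Dnaja1 (-0.14). With stimulation, these genes changed by less than the median shift of -0.19 or -0.21 that the factors remove. For fatty acid oxidation in the interaction, camera's direction was down (adjusted p = 0.893) and fry's was up (adjusted p = 0.0411). The median of the list, 0.01, lay above 0 but below that of all genes, 0.05. Camera compares a list with other genes and fry does not, so the tests ask different questions here.

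The replicate numbers did not pair the samples: over 18 pairs of libraries with the same number in different groups, the residuals had a mean r of -0.012, against 0.006 for other pairs. With the replicate number as a block, 6059 genes were called for Batf3 in non-stimulated cells, 4510 in stimulated cells, 12561 and 12947 for stimulation of control and Batf3 cells, and 3176 for the interaction. Leaving out 1 library gave 5522 to 6561 calls (2231 to 2970 up, 3103 to 3912 down) for Batf3 in non-stimulated cells and 3981 to 4740 (1909 to 2325 up, 2053 to 2415 down) in stimulated cells. Stimulation gave 12336 to 12819 (6093 to 6309 up, 6232 to 6524 down) in control cells and 12801 to 13231 (6196 to 6555 up, 6455 to 6799 down) in Batf3 cells. The interaction gave 2556 to 3196 (1565 to 2263 up, 824 to 1137 down), and 34 to 36.7% of its genes had the smaller response with the Batf3 vector. The correlation of the Batf3 effects was 0.355 to 0.382, with 974 to 1069 genes up and 1130 to 1366 down in both cultures; these fits tested 16033 to 16135 genes. On data simulated at this depth with 3 libraries per group, a 1.2-fold change was called in 56% of changed genes for Batf3 in non-stimulated cells, 42% in stimulated cells and 28% for the interaction. The simulation held no response to stimulation and changed no genes at low counts.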

Other observations

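The tests of background from genomic DNA, of depth by total counts and of lists with 1 library left out were chosen only after their results were seen. Several lists of metabolic and stress genes fell with the Batf3 vector in non-stimulated cells. For glycolysis 0 of 22 rose and 18 fell (0 and 19 adjusted over the list alone). The glycolysis list had a median of -0.26 (camera adjusted p = 5.24e-08), with the transporter gene Slc16a1 at -0.55 ± 0.04 and Hk2, a hexokinase, at -0.54 ± 0.04. Of the genes of cholesterol synthesis and uptake 1 of 23 rose and 16 fell (the same counts adjusted over the list alone). The cholesterol list had a median of -0.38 (camera adjusted p = 1.52e-06), with Idi1 at -0.65 ± 0.06. The amino acid and ATF4 response had no rise: 0 of 20 rose and 10 fell (the same counts adjusted over the list alone). The ATF4 list had a median of -0.21 (camera adjusted p = 2.64e-05), with Phgdh, the first enzyme of serine synthesis, at -0.57 ± 0.03 and Asns, asparagine synthetase, at -0.54 ± 0.05. For the unfolded protein response 1 of 15 rose and 13 fell (the same counts adjusted over the list alone). The unfolded protein list had a median of -0.29 (camera adjusted p = 6.36e-08), with the chaperone gene Hspa5 at -0.60 ± 0.02. For heat shock genes 0 of 10 rose and 9 fell (the same counts adjusted over the list alone). The heat shock list had a median of -0.61 (camera adjusted p = 2.06e-14), with Hspa1a and Hspa1b, which are close copies, at -1.20 ± 0.18 and -1.10 ± 0.15. For nuclear genes of oxidative phosphorylation 0 of 25 rose and 14 fell (the same counts adjusted over the list alone). The oxidative phosphorylation list had a median of -0.12 (camera adjusted p = 0.0141, and adjusted p = 0.0785 with an estimated correlation). For fatty acid oxidation 1 of 18 rose and 6 fell (the same counts adjusted over the list alone). The fatty acid list had a median of -0.08 (camera adjusted p = 0.248), with Acadl at -0.47 ± 0.04 and Cpt1a, which admits fatty acids to mitochondria, at 0.27 ± 0.05. In the opposite direction, for p53 targets 9 of 13 rose and 0 fell (the same counts adjusted over the list alone). The p53 list had a median of 0.21 (camera adjusted p = 0.00146), with Plk2 at 0.62 ± 0.11 and Zmat3 at 0.42 ± 0.05. For mitochondrially encoded genes 3 of 13 rose and 0 fell (the same counts adjusted over the list alone). The mitochondrial list had a median of 0.14 (camera adjusted p = 0.0174, and adjusted p = 0.556 with an estimated correlation), with mt-Cytb at 0.24 ± 0.03. This call was lost without control non-stimulated replicate 1 (adjusted p = 0.0548) or Batf3 non-stimulated replicate 2 (0.076).

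The same lists were measured in stimulated cells. For glycolysis 4 of 22 rose and 8 fell (the same counts adjusted over the list alone). The glycolysis list had a median of -0.04 (camera adjusted p = 0.38), which was 0.00 with library sizes alone. Pkm, a pyruvate kinase, rose by 0.36 ± 0.03 and Eno1 changed by -0.30 ± 0.03. For cholesterol synthesis 2 of 23 rose and 7 fell (3 and 7 adjusted over the list alone). The cholesterol list had a median of -0.07 (camera adjusted p = 0.131), with Hmgcs1 at -0.56 ± 0.07 and Lss at 0.53 ± 0.08. The amino acid and ATF4 response fell here too: 0 of 20 rose and 15 fell (0 and 16 adjusted over the list alone). The ATF4 list had a median of -0.22 (camera adjusted p = 1.16e-07), with Trib3 at -0.50 ± 0.05 and Chac1 at -0.58 ± 0.07. For the unfolded protein response 0 of 15 rose and 7 fell (0 and 9 adjusted over the list alone). The unfolded protein list had a median of -0.09 (camera adjusted p = 0.00698), with Herpud1 at -0.33 ± 0.03. For heat shock genes 1 of 10 rose and 5 fell (the same counts adjusted over the list alone). The heat shock list had a median of -0.13 (camera adjusted p = 0.0975), with Hspa8 at -0.17 ± 0.02 and Dnajb1 at 0.33 ± 0.06. Without Batf3 stimulated replicate 1 the list was called (adjusted p = 0.0494). For nuclear oxidative phosphorylation genes 0 of 25 rose and 6 fell (the same counts adjusted over the list alone). The oxidative phosphorylation list had a median of -0.06 (camera adjusted p = 0.115). Without Batf3 stimulated replicate 3 this list was called as well (adjusted p = 0.0449). For fatty acid oxidation 2 of 18 rose and 3 fell (the same counts adjusted over the list alone). The fatty acid list had a median of -0.08 (camera adjusted p = 0.38). For p53 targets 5 of 13 rose and 4 fell (the same counts adjusted over the list alone). The p53 list had a median of 0.05 (camera adjusted p = 0.549), with the cell cycle inhibitor gene Cdkn1a at -0.40 ± 0.03. For mitochondrially encoded genes 0 of 13 rose and 4 fell (the same counts adjusted over the list alone). The mitochondrial list had a median of -0.20 (camera adjusted p = 0.00186, and adjusted p = 0.407 with an estimated correlation), with mt-Nd5 at -0.23 ± 0.05. Much of this fall came from Batf3 stimulated replicate 3, where these genes held 1.64% of counts against 1.96 and 1.89% in the other 2 replicates. Without it the median was -0.11 (camera adjusted p = 0.0309).

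More genes had a count in Batf3 than in control libraries. Sequencing depth does not account for this, because it would need larger totals in Batf3 libraries. Their mean total was 14229950 counts against 14449961 in non-stimulated and 14255727 against 14317438 in stimulated cells, a ratio of at most 0.996. Thinning every library to 14211564 counts could therefore not have removed the difference, and it left 1406 and 629 genes. Whether the deposited counts had been brought to a common depth is not given in the sources used here. Background from genomic DNA, which covers genes without regard to their use, could contribute. Counts in 1453 odorant and vomeronasal receptor genes, which T cells are not known to use, were 1.43 times as high in Batf3 non-stimulated libraries (95% interval 1.25 to 1.62), beside 1.39 for other genes at low level, and 1.32 times (1.17 to 1.48), beside 1.27, in stimulated libraries. This explanation stays open and limits what calls at low counts can show, while a wider use of genes in Batf3 cells stays open as well, untested.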
